A study of Homo sapiens with 8 samples.

How the data were processed

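RNA from 8 tumours grown from MDA-MB-231 cells in nude mice, 4 per genotype, was extracted with Trizol and made into mRNA libraries, per the labels' protocols. The authors deposited 1 table of raw counts, whole numbers of reads per Ensembl gene, that were not normalized. Reads were trimmed with cutadapt, aligned with STAR 2.7.11a and counted with featureCounts 2.0.4 on hg38, per the submitters' processing notes, which also name DESeq2 1.46.0. The annotation release, the strand setting and the treatment of mouse reads are not given in the sources used here, so reads of conserved mouse transcripts may be among the counts. Every gene of the deposited table reaches more than 1 CPM in at least 4 libraries, so genes expressed in fewer tumours were left out before deposit and edgeR's own filter removed 0 genes. The 4 CDK4KO columns carry the numbers of the library names and were matched to CDK4KO replicates 1 to 4 through them.

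Symbols were found for 13524 of 13546 gene identifiers, and 22 have none. Coordinates come from GENCODE 29, which uses the same build (hg38), and were found for 13455 genes. Genotypes were compared in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr, robust dispersions and the quasi-likelihood test, with Benjamini-Hochberg adjustment over all 13546 genes and a threshold of 0.05. The common biological coefficient of variation was 11.7%. Fold changes are log2, CDK4KO minus CDK4WT, and each standard error is the one implied by the quasi-likelihood F statistic. The prior count of log2 CPM was 2. The tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined, except where the other parts name a test, fit or gene as chosen after.

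Gene lists were tested with camera (limma 3.58.1) on the edgeR fit, with a preset inter-gene correlation of 0.01, for lists with at least 5 measured genes (42 of 45). Camera with an estimated correlation and fry, a rotation test of the list alone, were alternatives. For each list the members past an adjusted p of 0.05 were counted over all genes and adjusted over the list alone. The adjustment over a list alone does not correct for the number of lists searched, and some genes, such as DES, belong to more than 1 list. List scores are the mean log2 CPM of the members per library. Library totals, list scores and summed CPM were compared with exact two-sided permutation tests over the 70 assignments of 4 and 4 libraries, where the smallest p is 0.0286.

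Named genes are CDK4, then up to 10 genes per direction with the largest log2 fold change among those with an adjusted p under 0.05, an average log2 CPM of at least 2 and complete separation of the genotypes, then up to 4 members with the smallest p of each list described, and the members of the CDK4/6, cyclin D and RB list that pass. FRRS1, further members of the hypoxia and glycolysis lists (ADM, VEGFA, SLC2A1, SLC2A3, GAPDH, TPI1 and LDHB) and the genes first named in the last part were chosen outside this rule, after their values were seen. Those of the last part are members of lists not described or belong to no list. Lists not described in the report had camera adjusted p of 0.973 (epithelial markers, and p53 targets, and heat shock), 0.274 (mesenchymal and invasion markers, and senescence-associated secreted factors), 0.269 (extracellular matrix, and lysosome and autophagy), 0.874 (TGF-beta response), 0.320 (cholesterol biosynthesis), 0.611 (fatty acid synthesis), 0.627 (type I interferon, MHC class I, and replication-dependent histones), 0.916 (ATF4), 0.284 (unfolded protein response) and 0.364 (immediate-early genes).

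The steps were tested on simulated data drawn from the means and library sizes of these 8 libraries for 13546 genes, with 200 genes changed in each of 5 simulations. Of genes changed 1.5-fold, 2-fold and 4-fold, 71.4%, 91.5% and 98.9% were recovered, and 6.00% of the calls were false. Of simulated lists of 30 genes, 5 of 5 shifted by -0.40 on the log2 scale and 0 of 5 without a shift were called. Simulated genes vary independently, unlike those of a pathway, so the list part of this test does not cover correlated members. No simulated library was made to stand apart, as CDK4KO replicates 1 and 4 did, so the recovered shares need not hold for the real libraries. There, CA9 and HK2, at log2 fold changes of -1.26 and -0.65, did not pass over all genes (edgeR adjusted p = 0.0648 and 0.0749).

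Library totals of 27841000 to 33618000 counts mean that spread between tumours rather than counting sets the error of most genes. The labels do not say that the tumours came from separate mice, so p-values measure only the spread between these libraries. Alternatives were DESeq2 1.42.0, limma voom with library quality weights, other scalings, filters and dispersion settings, the replicate number as a block, each library left out in turn, and the removal of host-list genes. Tests on 2 further patterns, the ribosomal protein list and the muscle and fat genes, were run and, with their results known, left out of the weighing of explanations, which is kept to 3 patterns.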

Results

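RNA was sequenced from tumours that formed after MDA-MB-231 cells, an established human triple-negative breast cancer line, were injected into nude mice. The injected cells either carried intact CDK4 (CDK4WT, 4 libraries) or were labelled CDK4 knockout (CDK4KO, 4 libraries). CDK4 is the cyclin D-dependent kinase that phosphorylates RB at the G1/S transition, and the series title links it to the cytoskeleton and to actomyosin contractility. The deposited table holds read counts for 13546 genes, with 27841000 to 33618000 counts per library. Totals overlapped between the genotypes, at 30520000 ± 2450000 in CDK4WT and 30920000 ± 1590000 in CDK4KO (SD, n = 4 each).

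CDK4 mRNA was not lower in the libraries labelled CDK4KO. The gene (ENSG00000135446, chromosome 12, 57747727 to 57756013, hg38) stood at 113 CPM ± 4.04 in CDK4WT and 122 CPM ± 9.66 in CDK4KO (SD, n = 4 each). The 4 CDK4WT tumours had 115, 107, 116 and 112 CPM, and the 4 CDK4KO tumours 111, 119, 125 and 134 CPM, replicates 1 to 4. The log2 fold change, CDK4KO minus CDK4WT, was 0.12 ± 0.07 (SE; edgeR quasi-likelihood test, adjusted p = 0.477). The labels do not say how the gene was disrupted, so this level checks neither the knockout nor the labels, and CDK4 exons overlap those of TSPAN31 in the annotation. CCND2, which encodes a cyclin D partner of CDK4, was the member of the CDK4/6, cyclin D and RB list that rose when p was adjusted over the list alone (1 of 24, against 0 over all genes). It went from 13.8 CPM ± 2.26 to 22.3 CPM ± 4.07 (log2 fold change 0.69 ± 0.15, list-alone adjusted p = 0.0173). CCND1, CDKN1A and CDKN2D did not pass either test, with log2 fold changes of 0.15 ± 0.09, 0.36 ± 0.12 and -0.17 ± 0.08.

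The first comparison asked which genes differ between CDK4KO and CDK4WT tumours. TRNP1, a nuclear protein studied in cortical development, had the largest increase among the called genes, from 8.61 CPM ± 1.54 to 19.5 CPM ± 4.09 (SD, n = 4 each; log2 fold change 1.18 ± 0.17, SE). PLD5, a phospholipase D family member, rose from 17.7 CPM ± 2.91 to 33.1 CPM ± 3.30 (0.90 ± 0.12). TTLL11, a tubulin polyglutamylase, and MYO5C, a class V myosin, rose by 0.64 ± 0.09 and 0.61 ± 0.07, MYO5C from 82.8 CPM ± 3.85 to 126 CPM ± 11.4. TUT7, a terminal uridylyltransferase, and CARD8, an inflammasome protein, rose by 0.48 ± 0.07 and 0.48 ± 0.06. L1CAM, a cell adhesion molecule, fell from 164 CPM ± 13.2 to 111 CPM ± 6.33 (-0.56 ± 0.07). FRRS1, a ferric reductase homologue named here after its values were seen because it lies below the expression minimum for named genes, fell from 2.78 CPM ± 0.24 to 1.31 CPM ± 0.11 (-1.08 ± 0.15). In each of these 8 genes all 4 libraries of one genotype lay above all 4 of the other.

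Those 8 genes, 6 higher and 2 lower in CDK4KO, are all that passed edgeR's quasi-likelihood test at an adjusted p of 0.05, with adjusted p from 0.0396 to 0.0408. At an unadjusted p of 0.05 there were 1758 genes (900 higher, 858 lower), where chance gives 677. The genotypes separated completely in 1040 genes, or 7.68%, where chance gives 2.86%. The count depends on the test: DESeq2 called 315 genes (170 higher, 145 lower) and limma voom with library quality weights 285 (163 higher, 122 lower), and both included all 8. It also rests on single libraries: 183 genes passed without CDK4KO replicate 1 and 17 without CDK4KO replicate 4, against 0 without CDK4WT replicate 4 or CDK4KO replicate 2 (1582 and 1688 at an unadjusted p of 0.05), and 1 without CDK4WT replicate 1, 2 or 3 or CDK4KO replicate 3. Of the 8 genes, 0 remained called without CDK4WT replicate 1, 2 or 4 or CDK4KO replicate 2 or 3, 1 without CDK4WT replicate 3, 7 without CDK4KO replicate 4 and 8 without CDK4KO replicate 1. Over these 8 fits each of the genes kept its direction, with log2 fold changes of 1.03 to 1.26 for TRNP1 and -0.61 to -0.53 for L1CAM, and adjusted p of the genes were at most 0.16. With library size alone as the scaling, 14 genes passed and 50% of them were higher, against 75% with TMM.

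**Figure D1:**
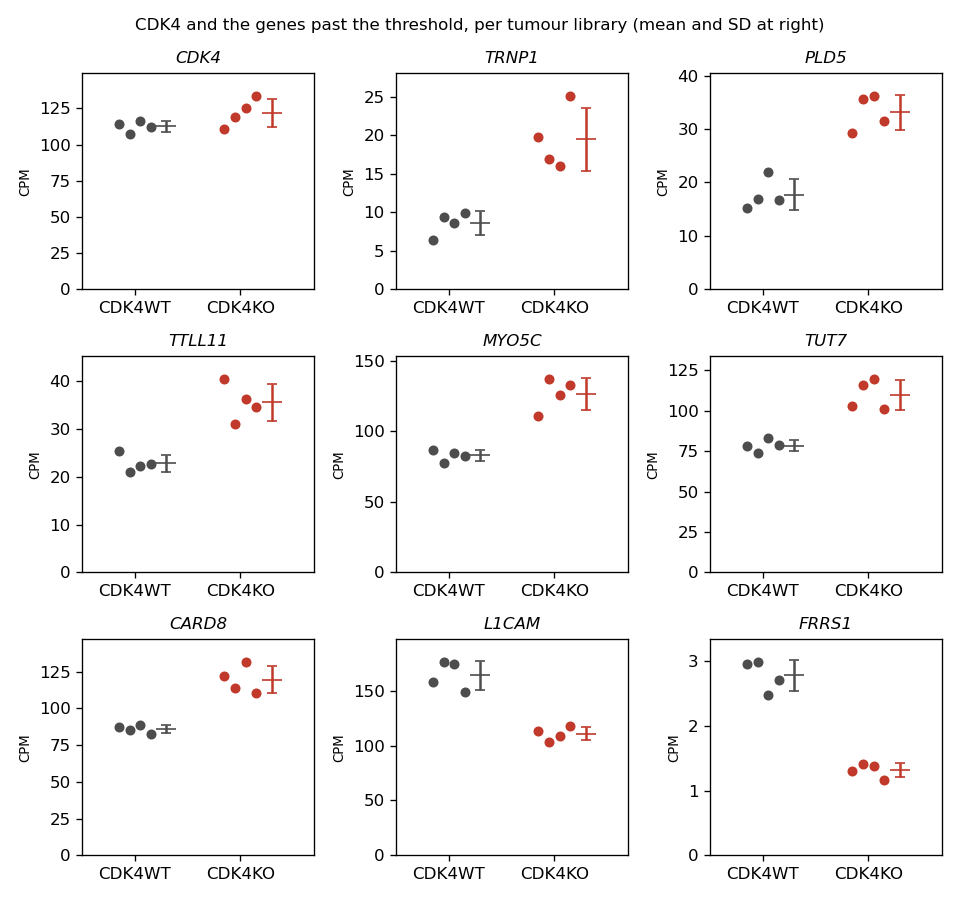
CPM (counts scaled by library size) of CDK4 and of the 8 called genes in each tumour library, CDK4WT in grey and CDK4KO in red, with the mean and SD of the 4 libraries at the right of each group. CDK4 overlaps between the genotypes, whereas TRNP1 ranges from 6.44 to 9.95 CPM in CDK4WT and from 16.0 to 25.1 CPM in CDK4KO.

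TRNP1 (ENSG00000253368) lies on chromosome 1 from 26993707 to 27000898, PLD5 (ENSG00000180287) on chromosome 1 from 242082986 to 242524696, and FRRS1 (ENSG00000156869) on chromosome 1 from 99708632 to 99766631. TTLL11 (ENSG00000175764) and TUT7 (ENSG00000083223) lie on chromosome 9, from 121821928 to 122093606 and from 86287733 to 86354454. MYO5C (ENSG00000128833) lies on chromosome 15 from 52192322 to 52295798, CARD8 (ENSG00000105483) on chromosome 19 from 48180770 to 48255946, and L1CAM (ENSG00000198910) on chromosome X from 153861514 to 153886174. All are annotated as protein-coding. Exons of MYO5C, CARD8 and L1CAM overlap other annotated genes, so a part of their counts is uncertain where the counting did not use strand.

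The libraries did not spread alike in both genotypes. The first principal component held 27.5% of the variance and placed all CDK4WT libraries on one side of all CDK4KO libraries (exact permutation p = 0.0286, the smallest that 4 against 4 can give). The second held 22.3% and set CDK4KO replicate 1 apart, at -31.3 against -1.5 to 9.5 in the other libraries. Mean correlations with the own group were 0.992 to 0.995 in CDK4WT and 0.985 to 0.989 in CDK4KO, where replicates 1 and 4 were lowest.

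The second comparison concerned the cytoskeleton, the subject in the series title. The actomyosin contractility list (myosin II chains and their regulators) had a median log2 fold change of 0.02 over 47 genes, 28 positive and 19 negative (0.007 without CDK4KO replicate 1, 0.037 without CDK4KO replicate 4). No member passed over all genes or adjusted over the list alone (camera adjusted p = 0.233). Its members with the smallest p were ARHGEF2, a guanine nucleotide exchange factor, at 0.33 ± 0.08, MYLK2 at 0.65 ± 0.20, SHROOM3 at 0.22 ± 0.08 and ARHGAP5 at 0.31 ± 0.11. ARHGEF2 had a median of 0.12 in its nearest neighbours on chromosome 1. MYLK2 was low, at a mean of 1.11 CPM in CDK4WT and 1.75 CPM in CDK4KO. In the list of actin filament assembly and turnover, AVIL, an actin-severing protein of the villin family, rose adjusted over the list alone (1 of 63, 0 over all genes), from 10.6 CPM ± 1.25 to 14.7 CPM ± 0.996. TAGLN2, an actin-binding protein of the transgelin family, fell in the SRF/MRTF list (1 of 33 over the list alone, 0 over all genes), from 427 CPM ± 22.01 to 322 CPM ± 32.6, with a median of -0.18 in its nearest neighbours on chromosome 1 against its own -0.41. In the focal adhesion and integrin list no member of 47 passed over the list alone or over all genes, and ITGB3 and ITGA6 had log2 fold changes of 0.55 ± 0.16 and 0.17 ± 0.07.

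None of these 4 lists passed camera, with adjusted p of 0.523 for actin filaments, 0.274 for focal adhesion and 0.834 for SRF/MRTF targets, although actomyosin and focal adhesion genes each reached 0.045 (higher) without CDK4KO replicate 4, against 0.625 and 0.864 with an estimated correlation and all libraries. The YAP/TAZ-TEAD targets had a median of -0.10 with 22 of 30 genes negative (-0.04 without CDK4KO replicate 4; adjusted p = 0.0533, and 0.864 as the adjusted p with an estimated correlation). AMOTL2, the member with the smallest p, went the other way, at 0.20 ± 0.06. DLC1, IGFBP3 and CCN1 stood at -0.58 ± 0.18, -0.37 ± 0.15 and -0.28 ± 0.12, and no member passed over the list alone or over all genes. That list passed without CDK4WT replicate 1 (0.0189) or 4 (0.00866), without CDK4KO replicate 2 (0.00741) or 3 (0.0209) and with library size only as the scaling (0.0489). Microtubule genes had a median of 0.03 (adjusted p = 0.274), with no member past the test over the list alone or over all genes. In the list of intermediate filaments and desmosomes (adjusted p = 0.627), DSP, the desmosomal plaque protein desmoplakin, fell adjusted over the list alone (1 of 26, 0 over all genes), by 0.31 ± 0.06 on the log2 scale.

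Cell cycle lists did not pass with all libraries. The G1/S and DNA replication list had a median of -0.02 over 50 genes (camera adjusted p = 0.453) and the G2/M and mitosis list -0.02 over 46 (0.916), and in neither did a member pass over the list alone or over all genes. RFC4 and RRM1 stood at -0.23 ± 0.11 and -0.13 ± 0.06, NUF2 at -0.32 ± 0.14 and FOXM1 at 0.22 ± 0.10. With an estimated correlation (0.546 and 0.679 among the members) the adjusted p over all libraries were 0.98 and 0.985. Without CDK4WT replicate 4 both lists passed camera with its preset correlation as lower in CDK4KO (medians -0.08 and -0.09, adjusted p = 0.000223 and 0.000177). Without CDK4WT replicate 2 both turned towards higher (medians 0.01 and 0.02, adjusted p = 0.931 and 0.180). RRM1, a subunit of ribonucleotide reductase, was at 145 CPM ± 10.3 in CDK4WT and 133 CPM ± 1.77 in CDK4KO.

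Hypoxia-response genes were lower in CDK4KO tumours. Of 29 measured members, 28 had a negative log2 fold change, the median was -0.43 (-0.28 without CDK4WT replicate 4), and 19 fell when p was adjusted over the list alone, against 0 over all genes. CA9, a carbonic anhydrase and HIF target, went from 43.2 CPM ± 11.9 to 18.0 CPM ± 3.07 (SD, n = 4 each; -1.26 ± 0.21, SE). PFKFB3 and PFKFB4, which make the glycolytic activator fructose 2,6-bisphosphate, stood at -0.76 ± 0.13 and -0.77 ± 0.13, INSIG2, a regulator of sterol synthesis, at -0.45 ± 0.10, and ADM and VEGFA, which encode adrenomedullin and the angiogenic factor VEGF-A, at -1.06 ± 0.25 and -0.54 ± 0.13. The mean log2 CPM of the list was lower in every CDK4KO library (6.40 to 6.74) than in every CDK4WT library (6.80 to 7.31; exact permutation p = 0.0286, adjusted p over the lists 0.300). Such scores separated the genotypes completely in 4 lists, each with these same p-values. The others were MYC targets and mitochondrially encoded genes, lower in CDK4KO, and Schwann cell and neuron genes, higher. Their differences were -0.07, -0.115 and 0.247, against -0.458 for the hypoxia list.

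Glycolysis genes were lower too, with a median of -0.21 and 17 of 20 negative, and 9 fell adjusted over the list alone, against 0 over all genes. Their mean log2 CPM overlapped between the genotypes, at 8.03 to 8.23 in CDK4KO and 8.20 to 8.54 in CDK4WT (exact permutation p = 0.0571, adjusted p over the lists 0.4). HK2, the inducible hexokinase, went from 361 CPM ± 59.5 to 230 CPM ± 26.7 (-0.65 ± 0.12), PFKP stood at -0.22 ± 0.07, and PGK1 at -0.52 ± 0.16. PGK1 lies in a stretch of chromosome X whose neighbouring genes were also lower. ALDOA, at -0.60 ± 0.12, shares exons with another annotated gene, which makes its count uncertain. SLC2A1 and SLC2A3, the glucose transporters GLUT1 and GLUT3, belong to both lists, at -0.50 ± 0.16 and -0.61 ± 0.19. GAPDH, TPI1 and LDHB had log2 fold changes of 0.07 ± 0.09, 0.02 ± 0.09 and -0.03 ± 0.12 and did not pass.

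Camera with its preset correlation gave adjusted p of 2.64e-25 for the hypoxia list and 1.47e-07 for glycolysis, and with an estimated correlation both adjusted p were 0.534. The counts rest in part on single libraries: 11 hypoxia and 2 glycolysis members passed without CDK4WT replicate 3, 12 and 2 without CDK4WT replicate 4, 13 and 3 without CDK4KO replicate 3, 14 and 2 without CDK4KO replicate 4, 17 and 6 without CDK4KO replicate 2, and 7 and 5 without CDK4KO libraries 1 and 4 together, a choice made after seeing the data.

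**Figure D2:**
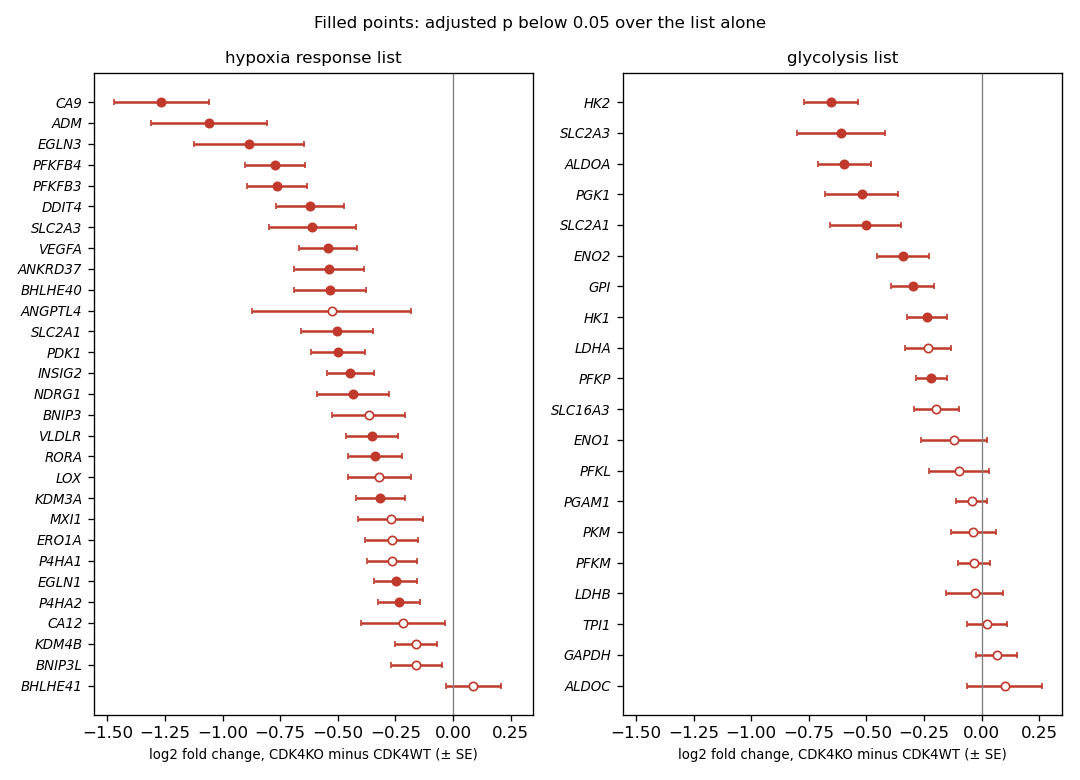
Log2 fold change, CDK4KO minus CDK4WT, with its standard error for every measured member of the hypoxia response list (29 genes, left) and the glycolysis list (20 genes, right). Filled points mark the 19 and 9 members with an adjusted p below 0.05 over the list alone, all of them below 0, and no member passed over all genes.

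Inflammatory genes of the NF-kB list had a median of -0.23 with 19 of 23 negative (-0.13 without CDK4WT replicate 4, -0.14 without CDK4KO replicate 1). CSF2, the cytokine GM-CSF, fell from 8.03 CPM ± 1.32 to 4.06 CPM ± 0.61 (-0.98 ± 0.15), PTGS2, the inducible cyclooxygenase COX-2, from 21.6 CPM ± 7.94 to 10.1 CPM ± 2.90, and CXCL1, a neutrophil-attracting chemokine, from 15.3 CPM ± 1.94 to 8.06 CPM ± 3.15. These 3 passed adjusted over the list alone, and 0 over all genes, where CSF2 had an adjusted p of 0.0508. BCL2A1 went the other way, at 0.81 ± 0.28, without passing. The list's camera adjusted p was 2.93e-05, and 0.625 was the adjusted p with an estimated correlation.

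Among EGFR/RAS/MAPK feedback genes the ligands AREG and EREG and the inhibitor SPRED1 rose adjusted over the list alone, AREG from 36.5 CPM ± 4.09 to 51.4 CPM ± 6.17 and EREG from 19.1 CPM ± 3.75 to 30.2 CPM ± 4.48, while TGFA, another EGFR ligand, fell by 0.35 ± 0.10 on the log2 scale. None of the 26 passed over all genes. The list had a median of 0.09 (0.14 without CDK4KO replicate 2) with 18 genes positive (camera adjusted p = 0.0211, and 0.534 as the adjusted p with an estimated correlation). The call was lost without CDK4WT replicate 1 (0.108) or CDK4KO replicate 1 (0.143).

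Lists of protein synthesis and respiration genes had medians slightly below 0, and none passed with an estimated correlation. Cytosolic ribosomal protein genes had a median of -0.14 (-0.08 without CDK4WT replicate 4) with 61 of 63 negative, among them RPL24 at -0.26 ± 0.08 and RPL38 at -0.33 ± 0.10, and no member passed adjusted over the list alone or over all genes. Many of these genes share sequence with processed pseudogenes, so their counts are uncertain. MYC targets and ribosome biogenesis genes had a median of -0.05 (-0.01 without CDK4KO replicate 1; 24 of 31 negative, NPM1 at -0.18 ± 0.07), nuclear-encoded oxidative phosphorylation genes -0.05 (-0.09 without CDK4KO replicate 4; 54 of 73 negative) and mitochondrially encoded genes -0.09 (-0.05 without CDK4WT replicate 1; 11 of 15 negative), each with 0 members past the test over the list alone or over all genes. SDHC, a subunit of respiratory complex II at -0.33 ± 0.10, lies in a stretch of chromosome 1, and COX7B, of complex IV at -0.41 ± 0.11, in a stretch of chromosome X, in which neighbouring genes were lower as well.

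Camera adjusted p for these 4 lists were 2.48e-13, 0.0211, 0.0126 and 0.0454, and the adjusted p with an estimated correlation were 0.743, 0.864, 0.864 and 0.743. Lists matched on length, GC content and expression mostly had medians of -0.056 to 0.006 (oxidative phosphorylation) and -0.094 to 0.016 (mitochondrially encoded). Both lists lay inside these ranges, so their lower medians do not stand apart from such lists. Ribosomal protein genes (-0.144, matched -0.046 to 0.014) and MYC targets (-0.052, matched -0.041 to 0.045) lay below. MYC targets lost the call without CDK4WT replicate 2 (0.0573) or CDK4KO replicate 1 (0.575), oxidative phosphorylation without CDK4KO replicate 2 (0.106) or 3 (0.0726), and mitochondrially encoded genes without CDK4WT replicate 1 (0.192) or 4 (0.0634) or CDK4KO replicate 2 (0.0578), 3 (0.0782) or 4 (0.0784), and without the genes of the host lists (0.0514). Of 42 lists tested, camera with the preset correlation called 11, 9 lower and 2 higher in CDK4KO, and with an estimated correlation or by fry it called 0. At an unadjusted p of 0.05, 3 lists passed with an estimated correlation and 6 by fry. In 27 of the 35 ways to split the 8 libraries into 4 and 4, the real one included, at least as many lists passed.

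Markers of host cells were measured as well, since a tumour in a mouse holds stroma and vessels and the handling of mouse reads is not given in the sources used here. Endothelial genes had a median of 0.13 with 11 of 14 positive (0.20 without CDK4KO replicate 1, 0.06 without CDK4KO replicate 3). ROBO4, an endothelial guidance receptor, rose from 110 CPM ± 6.64 to 159 CPM ± 23.97 and MMRN2, a vascular matrix protein, from 2.15 CPM ± 0.48 to 3.69 CPM ± 0.97, both adjusted over the list alone and 0 over all genes. The summed CPM of the endothelial list was 376 ± 18.0 in CDK4WT and 440 ± 26.7 in CDK4KO (exact permutation p = 0.0286, adjusted p = 0.257). ROBO4 and ESAM carry this rise and lie in a stretch of chromosome 11 whose neighbouring genes were also higher. The median in their nearest neighbours was 0.08, against their own log2 fold changes of 0.54 and 0.19. The other 12 members summed to 127 CPM ± 6.52 and 121 CPM ± 12.6 (exact permutation p = 0.571), a sum formed after the values were seen. The list's camera adjusted p was 0.0454, and 0.534 was the adjusted p with an estimated correlation. It was 0.0549, 0.0728, 0.0974, 0.0679 and 0.103 without CDK4WT replicate 1 or 3 or CDK4KO replicate 1, 2 or 3.

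Some skeletal muscle and adipocyte genes were lower in CDK4KO, at low levels. DES, CA3 and ACTA1 fell in the muscle list (3 of 8 adjusted over the list alone, 0 over all genes) and PLIN1 and LPL in the adipocyte list (2 of 5 over the list alone, 0 over all genes), all 5 at 23.0 CPM or less in each library. The summed CPM of the muscle list was 128 ± 13.8 in CDK4WT and 115 ± 13.4 in CDK4KO (exact permutation p = 0.257, adjusted p = 0.471) and that of the adipocyte list 30.04 ± 3.80 and 23.5 ± 1.57 (0.0571 and 0.257). Single CDK4WT tumours carried much of this: ACTA1 was at 23.0 CPM and ATP2A1 at 14.6 CPM in CDK4WT replicate 1, against 3.18 to 11.3 and 3.19 to 5.55 CPM in the other 7 libraries, and LPL was at 7.52 and 7.07 CPM in CDK4WT replicates 1 and 3, against 1.504 to 3.87 CPM elsewhere. Without CDK4WT replicate 1 the muscle list's median went from -0.69 to -0.30 and its camera adjusted p from 0.0201 to 0.06, against 0.625 with an estimated correlation and all libraries. That call was also lost without CDK4KO replicate 1 (0.0945) or 4 (0.071). The adipocyte list had a median of -0.28 and a camera adjusted p of 0.0211, lost with an estimated correlation (0.534) and without CDK4WT replicate 1 (0.06) or CDK4KO replicate 4 (0.0515).

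SYT1, a synaptic vesicle protein, rose in the Schwann cell and neuron list (1 of 5 adjusted over the list alone, 0 over all genes), from 40.5 CPM ± 6.20 to 57.0 CPM ± 10.8, and the list missed the threshold (median 0.18, and 0.06 without CDK4KO replicate 1 or 0.28 without CDK4KO replicate 3; camera adjusted p = 0.0533, against 0.0297 without CDK4WT replicate 4, 0.0458 without CDK4KO replicate 3, 0.0486 with upper-quartile scaling and 0.0478 with library size only, and 0.534 with an estimated correlation). Fibroblast, pericyte and smooth muscle, and macrophage and dendritic cell lists had medians of -0.12, -0.07 and 0.04 (camera adjusted p = 0.794, 0.523 and 0.794). DES was the only one of their members past the test over the list alone, with 0 over all genes. Of the leukocyte and keratinocyte lists 4 genes each were measured, and 0 of the erythrocyte list, so these 3 were not tested.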

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

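Of the tests in this part, the count of hypoxia members over other splits and the comparison of fold changes after thinning were chosen after the result was seen.

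The 8 genes called between CDK4KO and CDK4WT tumours were set against chance and technical sources. No other of the 35 splits of the 8 libraries called a gene with edgeR (1 of 35 gave as many as the real 8, highest other 0). At an unadjusted p of 0.05 the other splits gave at most 1447 genes against the real 1758. The real split thus had the most calls, but 1 of 35 is the smallest share these splits can give. The other splits also mix the genotypes, which widens their spread if the genotypes differ. The splits test the number of calls and not which genes are called, so chance cannot be excluded for each of the 8. All 8 remained called with the mean of the host lists as a covariate (19 calls in that fit). This mean pools lists that move apart and differed by only -0.071 between the genotypes (exact permutation p = 0.486). It could not have removed a difference, so reads of host cells stay open. Thinning every library to the smallest total, in a single random draw, ended 4 of the 8 calls and kept 4 (adjusted p 0.044 to 0.0539, from 0.0396 to 0.0408). The median absolute log2 fold change was 0.627 (median SE 0.0818) before and 0.62 (median SE 0.0852) after. For calls this close to the threshold a single draw cannot tell an effect of depth from noise of the draw, so an effect of depth on the number of calls stays open. Fold changes at 0.981 to 1.06 times the full ones and overlapping library totals argue against library size as the source of the differences. Windows of 25 neighbouring genes shifted together more often than with permuted gene positions, 81 of 527 windows against a mean of 5.27 (permutation p = 0.001, the smallest 1000 permutations can give), yet with the 100 permutations run per split the real split had 84 windows and 31 of 35 splits had as many (highest other 156), so regional shifts that could reflect copy-number or clonal differences run between single tumours, and a part that follows genotype cannot be told apart from them. Around the called genes themselves the neighbours' median reached 0.5 of the gene's own shift in 0 of 8. The highest share was 0.116, in CARD8. TRNP1, CARD8 and FRRS1 did lie in windows that shifted together in the gene's own direction, with shares of 0.077, 0.116 and 0.099. The other called genes did not. These shares argue against a copy-number change of the surrounding region as the source of most of each gene's shift. A small regional part, or a change confined to the gene itself, is not excluded. An effect of CDK4 loss or of the separate history of the knockout cells stays open, untested.

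The number of gene lists called stands differently. Camera with its preset correlation called 11 lists, and 27 of the 35 splits called at least as many (highest other 21), so chance cannot be excluded for that number. The members of a list vary together between tumours whatever the grouping, with estimated correlations of 0.654 for hypoxia genes and 0.694 for ribosomal protein genes against the preset 0.01, and no list passed with these estimates.

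For the hypoxia list itself some of the explanations tested did not account for the lower values. Over the splits, the 19 members called over the list alone were matched by 1 of 35, the real one, but the highest other split reached 17 members, with CDK4WT replicate 1 in the place of CDK4KO replicate 1. Lists matched on transcript length, GC content and expression had a median log2 fold change of 0.018 (95% between -0.03 and 0.06), against -0.43 for the list. The median was -0.47 after subtracting the median of each gene's 24 nearest genes, so regional shifts do not account for the whole of it, and -0.45 with the mean of the host lists as a covariate, which as above decides nothing, so host reads stay open. Oxygen supply, size or age of the tumours, which the labels do not give, and an effect of CDK4 loss stay open and untested, and 4 tumours per genotype with 1 close pair of libraries (6.74 and 6.80) leave the difference a hypothesis.

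Other values stood far from the rest of their group of 4, 15 of 244 groups tested where chance gives 12.2. CDK4KO replicate 2 had a total of 33307000 counts against 30057000 to 30209000 in the others of its group. CDK4KO replicate 1 had a mean log2 CPM of 6.41 for MYC targets, against 6.56 to 6.57. CDK4KO replicate 1 also had 65.6 CPM of MT-ATP8 (others 113 to 120) and 16.2 CPM of AVIL (14.02 to 14.34). CDK4KO replicate 4 had 114 CPM of SRC (78.0 to 82.4), 1037 CPM of ITGA6 (931 to 946) and 5.64 CPM of BCL2A1 (2.53 to 2.76). CDK4KO replicate 2 had 1033 CPM of MT-ND4L (792 to 801), and CDK4WT replicate 1 had 1147 (980 to 995). In CDK4WT replicate 1, CDKN1A was at 98.98 CPM (122 to 124), WASF3 at 16.7 CPM (14.4 to 14.8) and PPARG at 15.3 CPM (16.9 to 17.1). In CDK4WT replicate 3, TUFT1 was at 33.5 CPM (29.8 to 30.1) and COX7B at 54.6 CPM (56.6 to 56.8), and in CDK4WT replicate 4 EREG was at 24.8 CPM (17.2 to 17.4).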

How the results depend on the processing

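The fits without CDK4KO libraries 1 and 4, with the earlier quasi-likelihood method and of list members were chosen after the data were seen. The count of genes higher and lower, 6 and 2, was 13 and 5 under the stricter filter (9913 genes tested), 14 and 6 without host genes (13477 genes tested), 170 and 145 with DESeq2, 163 and 122 with limma voom, 277 and 170 without CDK4KO libraries 1 and 4, and 1 and 1 with an absolute log2 fold change of at least 1. With library size only it was 7 and 7. Leaving out single libraries gave 0 to 111 higher and 0 to 72 lower. Lists higher, 2, were 1 under the stricter filter, 1 without host genes, 1 without CDK4KO libraries 1 and 4, 0 with an estimated correlation and 0 by fry, and 0 to 4 without single libraries. Lists lower, 9, were 0 with an estimated correlation and 0 by fry, 7 under the stricter filter (which left 1 adipocyte and 1 muscle gene, too few for a test), 6 without host genes, 6 without CDK4KO libraries 1 and 4 and 7 to 11 without single libraries. Hypoxia members, 19, were 11 to 26 and glycolysis members, 9, were 2 to 12 without single libraries, and 7 and 5 without CDK4KO libraries 1 and 4. With the replicate number as a block (replicate block) 10 genes were higher and 3 lower, 5 of the 8 calls were kept, and 12 hypoxia members passed. Under the block the endothelial and mitochondrially encoded lists did not pass (0.086 each) and YAP/TAZ (0.0153) and Schwann cell and neuron (0.00983) lists did; same-numbered libraries deviated together with correlations of -0.031, -0.014, 0.003 and 0.194, so the numbers do not pair them. Directions turned without single libraries for G1/S (adjusted p 0.858 and 0.931), G2/M (0.18 to 0.792, and 0.961 without CDK4KO libraries 1 and 4), SRF/MRTF (0.326 to 0.984, and 0.262), YAP/TAZ (0.799 without those) and MBP (-0.048 without those), none of these turned values a call. Without CDK4WT replicate 4 the G1/S and G2/M lists kept direction and passed (0.000223 and 0.000177). The called muscle list's median turned to 0.05 under the stricter filter, which left 1 of its 8 genes. CDK4 stayed between 0.07 and 0.16 and uncalled in each alternative. Of the named genes' values under the alternatives, 1628 kept direction and side of the threshold, 89 passed it, 51 lost it and 1 reversed. Causes were not tested. The removal of the low-count filter removed no gene and is no test. Thinning to the smallest total ended 4 of the 8 calls, and over all 8 adjusted p lay close to the threshold (0.0396 to 0.0408 before, 0.044 to 0.0539 after). Fold changes stayed at 0.981 to 1.06 times the full ones, which thinning keeps by design.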

Other observations

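The genes first named in this part, the stretches of chromosomes and the correlations of CA3 were chosen after the results were seen. These genes are members of lists not described above or belong to no list. The cholesterol biosynthesis and ATF4 lists also held members past the test over the list alone, which are left out here.

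Matrix and signalling genes outside the lists described so far also moved in single members. COL6A2, a collagen VI chain, rose from 69.5 CPM ± 11.5 to 185 CPM ± 74.2 (log2 fold change 1.41 ± 0.28), the only 1 of 42 matrix genes adjusted over the list alone (0 over all genes), and COL6A1, its partner chain, stood at 324 CPM ± 7.06 and 486 CPM ± 117. ID1, an inhibitor of bHLH transcription factors in the TGF-beta list, rose from 35.2 CPM ± 9.27 to 70.5 CPM ± 17.4, EHF, an epithelial ETS factor, from 116 CPM ± 5.61 to 149 CPM ± 10.04 and S100A4, a calcium-binding protein of motile cells, from 262 CPM ± 17.0 to 350 CPM ± 43.6, each adjusted over its list alone and not over all genes. HILPDA, a hypoxia-induced lipid droplet protein kept in the lipid list, fell from 25.3 CPM ± 7.13 to 14.5 CPM ± 1.05 (list-alone adjusted p = 0.0222). DDB2, a p53 target in DNA repair, fell by 0.29 ± 0.07 on the log2 scale (list-alone adjusted p = 0.0319).

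MPRIP, which targets myosin phosphatase to actin, had 533 CPM ± 14.3 in CDK4WT and 694 CPM ± 64.1 in CDK4KO (0.38 ± 0.07, adjusted p = 0.0758, all CDK4KO libraries above all CDK4WT). LIMCH1, an activator of non-muscle myosin II, went the other way, at -0.43 ± 0.09 (adjusted p = 0.092), and neither passed. KISS1, a metastasis suppressor, stood at 36.7 CPM ± 6.42 in CDK4WT and 13.8 CPM ± 7.59 in CDK4KO (adjusted p = 0.190).

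SORCS3, a sorting receptor gene of chromosome 10 (104641101 to 105265235), was nearly silent in CDK4KO. Its 4 CDK4WT libraries held 943, 118, 328 and 158 counts (29.9, 3.48, 11.8 and 5.48 CPM) and its 4 CDK4KO libraries 6, 2, 4 and 3 counts, a ratio of summed counts, each scaled by the library totals, of 105 (95% exact interval 63.2 to 187, counting error only), and of 54.7 (32.9 to 98.4) without CDK4WT replicate 1. The adjusted p of edgeR's test was 0.0573. The deposited table keeps only genes above 1 CPM in at least 4 libraries. A gene this low in CDK4KO could be in it only with all 4 CDK4WT libraries above 1 CPM, so its complete separation followed from that filter.

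Stretches of neighbouring genes differed between tumours. On chromosome 1 from 160288686 to 186680427, 110 of 125 genes had a negative log2 fold change (median -0.19, none called), and the median deviation of these genes was 0.19, 0.09, 0.13 and -0.01 in CDK4WT replicates 1 to 4 and -0.01, -0.20, -0.27 and 0.06 in CDK4KO replicates 1 to 4. On chromosome X from 54530211 to 92114461, 63 of 75 genes were negative (median -0.20), with 0.12, 0.12, 0.09 and 0.13 in CDK4WT and 0.16, -0.13, -0.33 and -0.13 in CDK4KO. On chromosome 2 from 60756230 to 74557554 the negative median of -0.11 came from CDK4KO replicate 4 at -0.28, against 0.01 to 0.08 in the other libraries. In the chromosome 1 and X stretches lie SDHC and NUF2, and PGK1 and COX7B, whose own log2 fold changes of -0.33, -0.32, -0.52 and -0.41 compare with medians of -0.17, -0.19, -0.21 and -0.21 in their nearest neighbours.

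CA3, kept in the muscle list, followed the fat genes LPL and PLIN1 across the 8 libraries, each centred on its genotype, with Pearson r = 0.894 (exact permutation p = 0.059) and Spearman correlation 0.786 (exact p = 0.177), and r = 0.749 without the 2 libraries farthest from the median. Against ACTA1 and ATP2A1 Pearson r was 0.314 (exact p = 0.719) and the Spearman correlation 0.357 (exact p = 0.533). Neither of the 2 relations passed, with Benjamini-Hochberg adjusted p of 0.118 and 0.719.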
